A study of Mus musculus with 3 samples.

How the data were processed

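RNA was measured by sequencing total RNA from erythroblasts sorted from the peripheral blood of mouse embryos at E10.5. The 3 libraries, 1 in each of 3 groups, were grouped by their labels alone into control Ter119-high, Drosha-null cKO Ter119-high and cKO Ter119-low cells. The data are 2 tables in which the authors set each cKO library beside the control. Per the file headers and values, the tables hold the authors' expected counts per gene, which are estimated read counts before scaling, fractional for some genes. They also hold FPKM values, made by the authors by dividing the counts by gene length and library size, with 0.001 entered at 0 counts (744 genes of the Drosha-null and 943 of the Ter119-low library). The deposited log2 ratios are those of the 2 FPKM columns of each row. The deposited p-values and FDR come from the authors' comparison of 1 library with 1 library by a test they do not name there, and FDR values above 1 occur for 41 and 576 genes. The aligner, the counting program, the annotation and the genome build behind the tables are not given in the sources used here.

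The tables list 14640 and 14300 genes, of which 13882 are in both. Control counts were the same for all shared genes (0 differ), so the tables were joined by gene ID into 15058 genes, and a gene listed in 1 table alone (758 and 418 genes, 0 with control counts) was given 0 counts in the other. The expected counts were used rounded to whole numbers. A spreadsheet had turned 21 symbols into dates, and these were restored by gene ID from the reference table. Gene length, which differed between the tables for 2295 genes, was averaged. Locations and 3' UTRs were taken from GENCODE M21 on GRCm38, and 14057 of the genes (93.4%) have an annotated 3' UTR. The FPKM values entered only the alternatives.

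Total counts were 9497425 in the control, 9325814 in the Drosha-null and 9418474 in the Ter119-low library, with 13277, 13894 and 13352 genes detected. Ribosomal RNA took 28.7%, 27.9% and 28.5% of the counts, and the 10 most abundant genes 54.7%, 45.9% and 52.6%. Scaling was by TMM in edgeR 4.0.16 under R 4.3.3, with factors of 0.885, 1.19 and 0.946. The floor of 3 counts, used as the bound for genes at 0 counts, came to 0.357, 0.269 and 0.337 CPM. For each pair of libraries the log2 ratio was computed with 0.5 counts added and an exact 95% Clopper-Pearson counting interval, among genes at 1 or more CPM in either library. With 1 library per group no test across conditions was fitted. Genes were counted as higher or lower when the ratio was 2 or more either way and the interval excluded 1. The computations used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.

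For each of 34 gene lists (989 entries, 842 matched) the median log2 ratio of the measured members was set among 10000 random lists of the same size, matched on 20 bins of expression. Lists with fewer than 3 measured members were given no percentile. Genes with a 7-base 3' UTR match to the seed of 7 microRNA families were compared in the same way with random sets matched on 3' UTR length and expression, and with 20 shuffled versions of each seed. The overlap of the 2 comparisons with the control was set beside the number expected of independent lists. It was also set beside 100 simulations of counting noise in the cKO libraries, with the control counts held fixed. The comparisons, lists, seeds, size rule and the rule for the genes named were chosen before the data were examined. That rule takes Drosha, Dgcr8, Dicer1, all measured globins, Tfrc, Slc4a1, Alas2, Gata1, Klf1, Gata2, Kit, Cdh5 and Cdkn1a. It also takes, per comparison, the 8 highest and 8 lowest genes by the interval bound nearest 0 with at least 10 CPM in the higher library and without predicted genes. From each list it takes the 2 most abundant members and the 2 with the largest ratios, and from lists outside their random range the highest and lowest member. For markers of other cells the 3 most abundant members of each list are given in every library. Some genes that the rule takes are not reported here.

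The procedure was tested on simulated data with 50 genes changed at each of 4 folds. For the Drosha-null library against the control, with 10563 genes in the step, 3, 31, 47 and 50 of 50 genes were recovered at folds of 1.5, 2, 3 and 5. For the Ter119-low library against the control, with 10441 genes, the recovered numbers were 2, 27, 49 and 49, and for the Drosha-null against the Ter119-low library, with 10615 genes, 1, 29, 49 and 49. In each comparison 0 were called in the wrong direction. Of unchanged genes, 65 of 10363, 65 of 10242 and 75 of 10416 were called, and the interval held 1 for 95.6%, 95.5% and 95.3%. The simulated libraries held counting noise alone, which is what the interval assumes. These values therefore give no error rate for real libraries, which also vary between pools and preparations. Of 40 random lists of 25 unchanged genes, 40, 37 and 39 lay inside the central 95%, and a list raised 1.4-fold lay at percentile 100 in all. With 0%, 10% and 20% of Drosha-null RNA mixed into a control library, the share estimated by total counts from higher genes was 0.183%, 9.58% and 20.1%, and from lower genes −0.752%, 9.84% and 20.5%. The mixtures were built from shares of total counts, so total counts return the share by construction.

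The alternatives tried were scaling by total counts, by the median of ratios as in DESeq2 1.42.0, and by total counts without globin genes, the authors' deposited ratios or FPKM values, no abundance minimum or 10 CPM, 5 counts added, size alone with no interval, folds of 1.5 and 4, an 8-base seed match and, for the authors' deposited FDR, 0.001. Scaling without globin and ribosomal RNA, and random lists and sets matched on gene length as well, were added after the data were examined. Reads were not aligned here, exons of Drosha could not be counted apart, and microRNAs themselves were not analysed here.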

Results

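The series measured the transcriptomes of erythroblasts, the nucleated precursors of red blood cells, from mouse embryos at E10.5. Cells were sorted from peripheral blood by CD71, the transferrin receptor, and Ter119, a red-cell surface antigen that increases as erythroblasts mature. Drosha is the nuclear enzyme that cuts primary microRNA transcripts, and in the conditional knockout (cKO) embryos a floxed Drosha was deleted with a Cre recombinase driven by the endothelial gene Cdh5. The 3 libraries, of which each group had 1, were CD71-positive Ter119-high cells of control embryos, CD71-positive Ter119-high cells of cKO embryos whose label gives Drosha as null (the Drosha-null library), and CD71-positive Ter119-low cells of cKO embryos whose label gives Drosha as abundant as in wild type (the Ter119-low library). The design text describes pools of 5 embryos. Total counts per library were 9497425 for the control, 9325814 for the Drosha-null and 9418474 for the Ter119-low library. There are no replicates, so no difference could be set against a spread between embryos or pools. Intervals and floors cover counting error only, except where a bootstrap over genes is named, and reads without molecular identifiers are not independent molecules. Ratios are log2 ratios of counts scaled by TMM with 0.5 counts added, with 95% Clopper-Pearson counting intervals. A gene was called higher or lower in a library when its ratio was at least 2 either way and its interval excluded 1.

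Drosha itself was lowest in the Drosha-null library. The gene (chromosome 15, 12824815 to 12935291, plus strand, GRCm38) had 324 counts in the control, 122 in the Drosha-null and 244 in the Ter119-low library. The log2 ratio to the control was −1.81 in the Drosha-null library (interval −2.13 to −1.51) and −0.49 in the Ter119-low library (−0.74 to −0.25). The Ter119-low library therefore held less Drosha RNA than the control, although its label gives the same abundance. Between the cKO libraries the log2 ratio, Drosha-null over Ter119-low, was −1.32 (−1.65 to −1.0). Counts over the whole gene also take in reads outside the deleted part, so the remaining 122 counts do not measure intact Drosha RNA.

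The first comparison, Drosha-null against control, sets cells of the same gate beside each other, labelled as Drosha null and as wild type for Drosha, and asks how their transcriptomes differ. Dgcr8, the RNA-binding partner of Drosha whose own messenger RNA the pair is known to cut, was higher in the Drosha-null library (log2 ratio 1.98), as was the cell cycle inhibitor Cdkn1a (2.72). Genes with 3' UTR sites for the erythroid microRNA miR-451 were higher as a set, with a median of 0.59. Embryonic globins, genes of heme synthesis and iron handling, cytosolic ribosomal protein genes and snoRNA host transcripts had list medians of −1.11, −0.65, −0.82 and −1.28. Of 10769 genes at 1 or more CPM (counts scaled to library size) in either library, 1340 were called higher and 832 lower.

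Among the 16 measured genes of the Microprocessor and microRNA machinery, 5 were called higher and 1, Drosha, lower, and the median of 0.48 lay at percentile 99.98 of 10000 random lists matched on expression. Dgcr8 (chromosome 16, 18253948 to 18289246, minus strand) had 317 counts in the control and 1658 in the Drosha-null library, with an interval of 1.81 to 2.16. Prkra, which encodes a protein partner of Dicer, had 18 and 107 counts (log2 ratio 2.14, 1.44 to 2.97). Tnrc6b, which encodes a silencing partner of Argonaute proteins, stood at 0.91 and Dicer1 at 0.45, both under the size rule. Of 5 measured messenger RNAs reported in the literature as direct Microprocessor targets, Dgcr8 and Kif1b (1.42) were called higher, and the median of 0.39 lay inside the range of random lists at percentile 77.9.

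Of 23 measured genes on the list of reported microRNA targets, 6 were called higher and 0 lower (median 0.55, percentile 99.99). They included Ywhaz, a 14-3-3 adaptor gene and known miR-451 target, with 1903 counts in the control and 6662 in the Drosha-null library (1.4, 1.33 to 1.47). Cdkn1a (chromosome 17, 29090976 to 29100727, plus strand), which is on this list and on that of p53 targets, had 83 and 729 counts, a ratio of 6.59 (interval of the log2 ratio 2.40 to 3.07). Cyclin genes on the list went the other way without reaching the size rule, with Ccnd3 at −0.49 and Ccne1 at −0.83. Host transcripts of microRNAs, 10 of them measured, had 3 called higher and 3 lower around a median of −0.47 (percentile 6.53). In every comparison this list also holds Gas5 and Snhg1, which are on the list of snoRNA hosts too. Both stood below the control here, so the list does not describe microRNA hosts alone. Among these hosts H19 stood at −1.43, while Dleu2, host of miR-15a and miR-16-1, stood at 1.59.

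The seed-site comparison asked the same of all genes with an annotated 3' UTR. The 217 genes with a 7-base miR-451 site had a median of 0.59, against 0.11 (−0.01 to 0.23) in random sets matched on 3' UTR length and expression, at percentile 100. Of these, 70 (32.3%) were called higher and 7 lower, against 12.2% higher among genes without a site. The 73 site genes at 20 or more CPM in the control had a median of 0.0991, against −0.09 (−0.21 to 0.07) in their matched sets, at percentile 99.4. This cut is on the control, the denominator of the ratio, so the medians of 0.0991 and 0.59 have different baselines. Sites of miR-92/25 (819 genes, median 0.30), miR-17/20/93 (1602 genes, 0.20) and miR-144-3p (1503 genes, 0.17) also lay at percentile 100. Each seed was set beside 20 shuffled versions: 0 of 20 had an excess over matched sets as large for miR-451, miR-92/25 and miR-17/20/93, and 1 of 20 for miR-144-3p. For miR-92/25 the highest shuffled excess, 0.17, was close to its own, 0.18. Sites of let-7 (0.13, percentile 77.2), miR-15/16 (0.10, percentile 83.1) and miR-486-5p (0.16, percentile 93.3) lay inside their random ranges. With 8-base sites let-7 (0.23) and miR-15/16 (0.22) lay above theirs, and miR-486-5p (0.17) stayed inside. The genes of miR-144 and miR-451 lie side by side on chromosome 11, at 78073005 to 78073070 and 78073170 to 78073241.

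**Figure D1:**
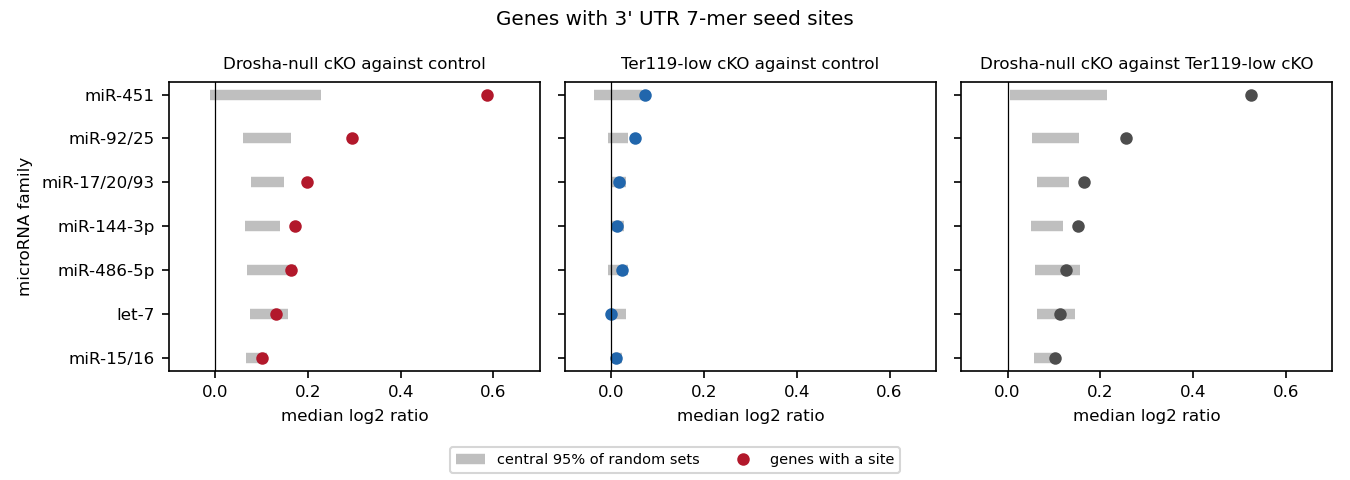
Median log2 ratio of genes with a 7-base 3' UTR site for each of 7 microRNA families (points), in 1 panel per comparison, with the central 95% of 10000 matched random sets (grey bars). Genes with miR-451 sites stand at 0.59 in the Drosha-null library against the control and at 0.07 in the Ter119-low library.

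Globins, heme and iron genes and erythroid regulators had list medians below their random ranges in the Drosha-null library. The 3 embryonic globins, which make up the hemoglobin of primitive erythroblasts, were all below 0 under every scaling, with Hbb-bh1 at −1.70 (328997 counts in the control, 133985 in the Drosha-null library), Hbb-y at −1.11 and Hba-x at −0.73. Globin genes took 25.01% of control counts (Clopper-Pearson interval 24.98% to 25.04%) and 17.06% of Drosha-null counts (17.04% to 17.09%). The 5 adult globins had a median of −0.82, with Hba-a1 at −1.22, Hba-a2 at −1.71, Hbb-b1 at −0.82, Hbb-b2 at 1.12 and Beta-s at 0.22. These copies are nearly identical and carry fractional counts, so their single values are uncertain. The percentiles of both globin lists, 0.505 and 1.42, became 3.2 and 27.8 when the random lists were matched on gene length as well.

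On the list of heme synthesis and iron handling, 0 of 26 measured genes were called higher and 4 lower (median −0.65, percentile 0.01). The mitochondrial iron importer Slc25a37 had 29361 counts in the control and 10429 in the Drosha-null library (−1.90), and the glycine carrier Slc25a38 stood at −1.52. The first enzyme of heme synthesis in red cells, Alas2, stood at −0.66, the transferrin receptor Tfrc at −0.95 and the iron importer Slc11a2 at 0.33. Erythroid regulators, 28 measured, had 3 called higher and 7 lower (median −0.53, percentile 0.01), with Hemgn at −1.42, Socs3 at −1.65, Nfia at 2.02, Tal1 at −0.67 and Klf1 at −0.57. Gata1, the central erythroid transcription factor, stood at −0.20 by TMM and above 0 when scaled by total counts.

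The list of red-cell membrane and cytoskeleton genes had a median of −0.37 (percentile 4.82), which turned positive under total-count scaling. Its anion exchanger Slc4a1 stood at −1.21, past the size rule by TMM but not by total counts (−0.77). Mpp1 (2.31) and Cd47 (2.11) stood above the control. Terminal maturation genes lay inside the random range (median −0.24, percentile 14.9, positive by total counts), yet Bpgm, which makes the hemoglobin ligand 2,3-bisphosphoglycerate, was among the lowest genes of the comparison (4550 and 1170 counts, −2.37), and Trim58 stood at −1.52. Pklr, the red-cell pyruvate kinase, stood at −2.46, and the metallothioneins Mt2 and Mt1, which bind zinc and copper, at −3.60 and −2.76.

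**Figure D2:**
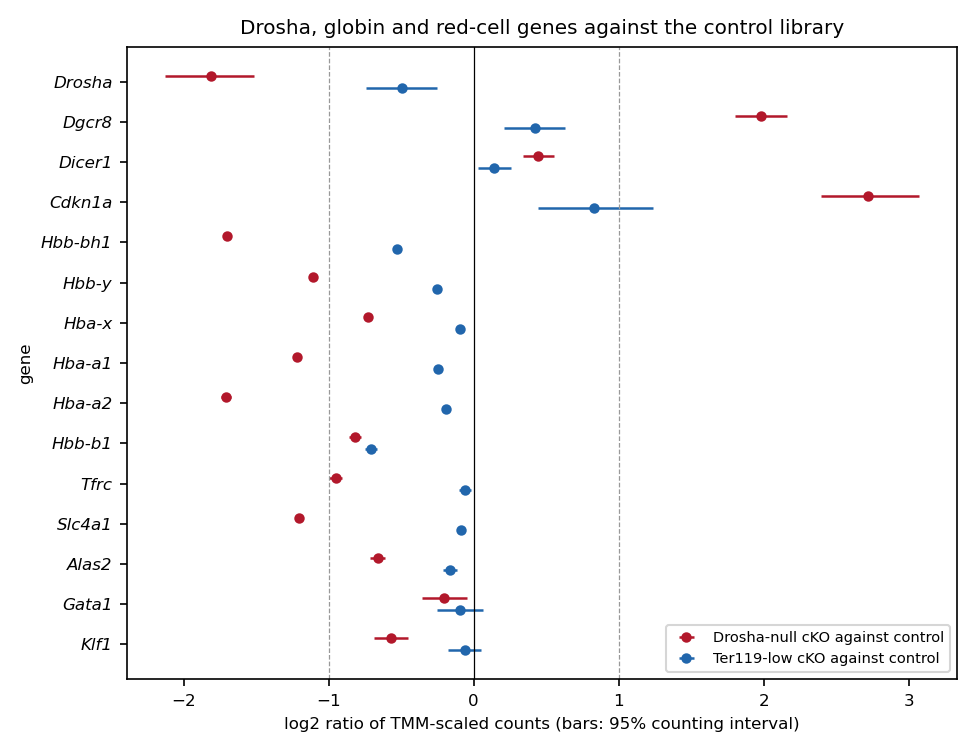
Log2 ratios to the control of genes fixed before the data were examined, in the Drosha-null (red) and Ter119-low (blue) libraries, with 95% counting intervals as bars and dashed lines at −1 and 1. Drosha stands at −1.81 and −0.49 and Dgcr8 at 1.98 and 0.42, while Gata1, at −0.20 and −0.09 here, lies above 0 in both when scaled by total counts.

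Ribosomal protein, ribosome biogenesis and snoRNA host lists had medians below their random ranges in the Drosha-null library. All 82 measured cytosolic ribosomal protein genes were below 0 by TMM, with 3 of them above 0 by total counts, and 13 were called lower (median −0.82, percentile 0, random range −0.38 to −0.14). Rps2 stood at −0.79, Rpl4 at −0.48 and Rplp1 at −1.31. The lowest was Rpl30, at −3.31 with fractional counts and therefore uncertain. Mitochondrial ribosomal protein genes, encoded in the nucleus, had 18 of 78 called lower and 0 higher (median −0.67, percentile 0), with Mrpl42 at −1.99, Mrps18a at −1.85 and Mrps31 at 0.49. Ribosome biogenesis genes had 4 of 41 called lower (median −0.40, percentile 0.04, and above 0 by total counts), including the H/ACA particle genes Nhp2 (−1.59) and Nop10 (−1.45), while nucleolin, Ncl, stood at −0.41 by TMM and above 0 by total counts. The 24 measured translation factors lay inside the random range (−0.43, percentile 6.48). Among 18 transcripts that host snoRNAs, 11 were called lower and 0 higher (median −1.28, percentile 0), with Gas5 at −1.35 (2297 and 1197 counts), Snhg1 at −1.04 and Snhg3 at −2.26.

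The ribosomal protein and snoRNA host lists consist of short genes, and the log2 ratio rose with gene length across all genes (Spearman's rho 0.31 over 10769 genes, which are not independent replicates). The shortest of 10 length classes had a median of −0.59, with 53 genes called higher and 250 lower, and the longest 0.30, with 185 higher and 33 lower. Against random lists also matched on gene length, the cytosolic and mitochondrial ribosomal proteins, ribosome biogenesis, snoRNA hosts, heme and erythroid regulator lists kept their side of the random range. The globin, interferon-stimulated and replication-dependent histone lists did not, and the membrane list moved below it (percentile 0.53).

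**Figure D3:**
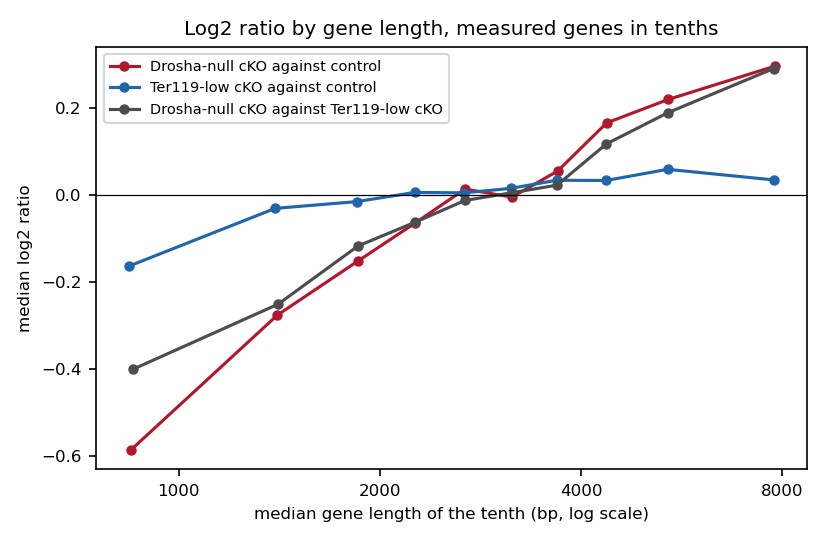
Median log2 ratio (vertical axis) of the measured genes in 10 classes of gene length in bp (horizontal axis, log scale), 1 line per comparison. In the Drosha-null library against the control the medians run from −0.59 for the shortest to 0.30 for the longest genes, and in the Ter119-low library against the control from −0.16 to 0.03.

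Of 26 measured p53 target genes, 11 were called higher and 3 lower (median 0.64, percentile 99.99). Ccng1, which encodes cyclin G1, had 742 counts in the control and 3388 in the Drosha-null library (1.78, 1.67 to 1.90). Eda2r had 0 and 40 counts, at least 10.1-fold higher against a floor of 3 counts, and 9630033F20Rik (reference symbol Tigar) had 0 and 24, at least 6.03-fold higher. Mdm2, the p53 ubiquitin ligase and itself a p53 target, stood at 0.30, and Gadd45a at −1.45. On the apoptosis list 5 of 23 genes were called higher and 0 lower (median 0.55, percentile 99.7). The initiator caspase Casp8 had 12 and 175 counts (3.41, 2.62 to 4.44) and Casp6 stood at 1.89, while the survival gene Bcl2l1 stood at −0.86.

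Cell cycle genes did not differ in 1 direction. Mitosis genes had a median of 0.28 (percentile 100), although of 34 only Anln (1.61) was called higher and Cenpa (−1.15) lower, and Top2a and Mki67 stood at 0.56 and −0.56. S-phase genes lay inside the random range (−0.19, percentile 18.7, positive by total counts), with Orc1 at −1.24 and Rrm2 at −1.01. Replication-dependent histone genes had 2 of 28 called higher and 8 lower (median −0.59, percentile 0, or 15.7 against length-matched lists), with Hist1h3d at −2.06 and Hist1h4d at −0.68. Hist1h2ad had 0 counts in the control and 26 in the Drosha-null library, at least 6.53-fold higher. Histone genes are near-identical copies, so single members are uncertain.

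Glycolysis and hypoxia genes were higher as a list, with 8 of 27 called higher and 1 lower (median 0.43, percentile 99.98). Egln3, an oxygen-sensing prolyl hydroxylase and target of hypoxia-inducible factors, had 7 and 89 counts (3.18), Aldoc had 2 and 33 (ratio 10.4, interval 3.18 to 107), and the abundant Gapdh and Ldha stood at 0.44 and 0.38. Genes of the integrated stress response had 1 of 24 called higher and 6 lower (median −0.54, percentile 0.02), with Trib3 at −2.34, Atf5 at −1.44 and Ddit4 at 1.34. Of 11 measured interferon-stimulated genes, 5 were called higher (median 0.74, percentile 98.2, or 95.1 against length-matched lists). The highest were Parp14 (5 and 95 counts, 3.73) and Bst2 (5 and 41, 2.53), while among genes at 10 or more CPM the list had no excess. Immediate early and heat shock genes lay inside the random range (−0.15, percentile 33.7, positive by total counts), with Junb at 2.02 and Hspa8 at −0.17 by TMM, above 0 by total counts.

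The genes with the largest differences by counting interval included the α4 integrin gene Itga4, with 23 counts in the control and 1015 in the Drosha-null library (5.03, 4.46 to 5.72) and Psd3 (3.55). Ttc39b had 2 and 129 counts (ratio 40.2, interval 13.2 to 406) and Tspan8 had 4 and 122 (4.38). The lowest included Synb, an envelope gene of retroviral origin known from placenta, with 109 and 6 counts (−4.47), Tinagl1 (−4.01) and the transcription factor gene Lmx1a (−2.22). Runx1, a transcription factor required for definitive blood stem cell formation, had 80 and 836 counts (2.97, 2.65 to 3.33). On the list of hematopoietic progenitor genes 6 of 17 were called higher and 1 lower, with a median inside the random range (0.37, percentile 88.4). The list included the cytokine receptor subunit gene Csf2rb (2966 and 16030 counts, 2.03, fractional), whereas Hoxa9 had 14 and 3 counts (ratio, control over Drosha-null, 5.36, interval 1.73 to 33.6), Kit 12 and 6, and Ikzf1 stood at −0.09 by TMM and above 0 by total counts. The most abundant progenitor genes were Csf2rb, Ikzf1 and Myc, the last 2 with 2767 and 1956 counts in the control, 3438 and 1474 in the Drosha-null and 2780 and 1770 in the Ter119-low library, where Csf2rb had 3901.

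Counts of marker genes of other cells are given here for the control, Drosha-null and Ter119-low libraries in turn. Cardiac muscle genes had 5 of 6 called higher in the Drosha-null library (median 3.37, percentile 100, or 1.94 with genes at 0 counts placed at their bound), with Ttn at 37, 181 and 42 counts, Actc1 at 19, 86 and 9 and Tnnt2 at 16, 20 and 0. Smyd1, a muscle methyltransferase gene, had 0, 27 and 0. Endothelial genes lay inside the random range (12 measured, 2 higher and 1 lower, 0.95, percentile 89.9), with Pecam1 at 3, 55 and 4 counts (ratio of the Drosha-null library to the control 12.2, interval 4.49 to 69.1), Vwf at 15, 38 and 26, Cd93 at 15, 32 and 18, Egfl7 at 12, 32 and 20 and Cdh5 at 12, 32 and 16. Mesenchyme genes (12 measured, 5 higher, 0.75, percentile 95) included Fn1, which encodes fibronectin, at 741, 2683 and 621 counts, Sparc at 56, 65 and 47 and Meox1 at 23, 68 and 25. Megakaryocyte genes (8 measured, 2 higher, 0.35, percentile 74.0) included Itgb3 at 312, 557 and 372, Itga2b at 79, 126 and 96 and Tubb1 at 42, 40 and 50. Macrophage genes (4 measured, 0 called, −0.44, percentile 16.2) included Lyz2 at 22, 27 and 18, Dab2 at 22, 28 and 16 and Cd68 at 17, 13 and 5. Neural genes (14 measured, 3 lower, −0.19, percentile 15.6, positive by total counts) included Nes at 85, 174 and 104, Tubb3 at 59, 88 and 54 and Ncam1 at 37, 83 and 50. Of the granulocyte list 2 genes were measured, Gsr (334, 428 and 353 counts) and Mpo (6, 23 and 0), of the yolk sac endoderm and liver list 0, and 0 of the genes encoded in mitochondria matched the tables.

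**Figure D4:**
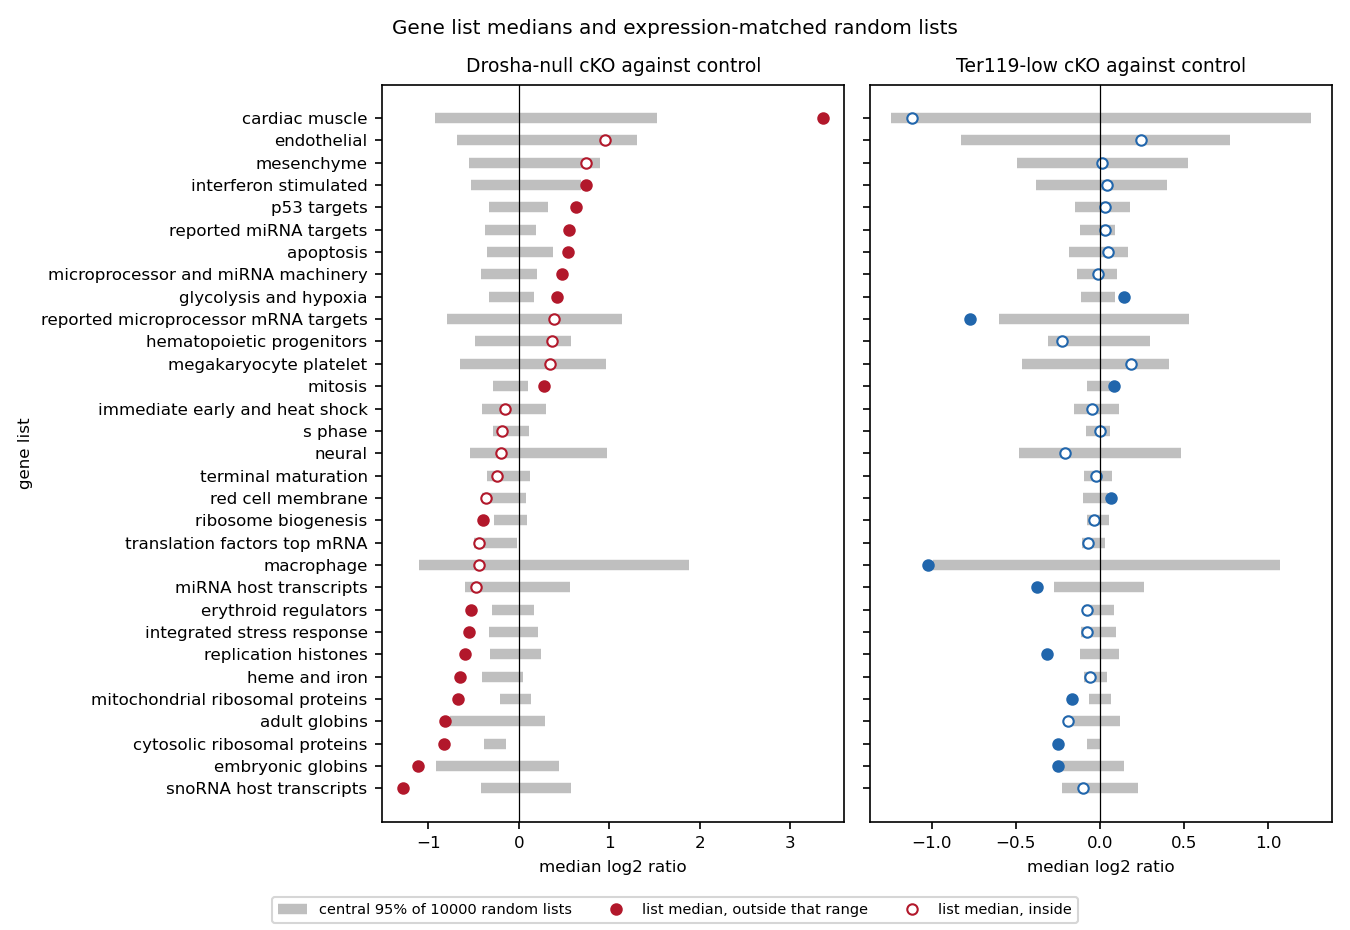
Median log2 ratio to the control of 31 gene lists (points, filled where outside the central 95% of 10000 expression-matched random lists, grey bars), for the Drosha-null library (left) and the Ter119-low library (right), whose horizontal axes differ in scale. Of the 31 medians, 6 on the left and 8 on the right change sign under another scaling, among them S phase and terminal maturation on the left and heme and iron on the right.

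The 2 libraries differed in composition, so scaling moves the balance of this comparison. Scaling by total counts raised log2 ratios by 0.43, leaving out globin genes by 0.29, and leaving out globin and ribosomal RNA by 0.18, less for genes at few counts, and the share of called genes that were higher went from 61.7% to 89.5%, 83.0% and 75.5%, or 85.6% with the authors' deposited log2 ratio.

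The second comparison, Ter119-low against control, sets cKO cells that by their label keep Drosha beside control cells, and differs in gate and genotype together. The Ter119-low library was close to the control, with 307 genes called higher and 290 lower of 10591 measured. Xist, the RNA that coats the inactive X chromosome, was higher (1818 counts in the control, 3958 in the Ter119-low library, log2 ratio 1.04), and so was the X-linked gene Mid1 (1.48). Replication-dependent histone genes, cytosolic and mitochondrial ribosomal protein genes and embryonic globins had list medians below their random ranges, at −0.32, −0.25, −0.16 and −0.25. Pearson's r of log2(CPM + 1) across genes was 0.983, against 0.941 for the Drosha-null library and the control.

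The microRNA machinery, reported microRNA targets and p53 targets lay inside their random ranges as lists. The machinery list had a median of −0.01 (16 measured, 0 called, percentile 54.2, positive by total counts), with Dgcr8 at 0.42 (0.21 to 0.63) and Dicer1 at 0.14. Reported microRNA targets stood at 0.03 (22 measured, percentile 81.1). Cdkn1a had 83 counts in the control and 157 in the Ter119-low library (0.83, 0.44 to 1.24). Of 25 p53 targets 2 were called higher (median 0.03, percentile 58.9): Trp53inp1 with 28 and 65 counts (1.12) and Eda2r with 0 and 9, at least 2.83-fold higher. Genes with miR-451 sites had a median of 0.07 against a random range of −0.04 to 0.07 (percentile 98.6). Of 20 shuffled seeds 0 had an excess as large, though the highest, 0.052, was close to its own, 0.055. The 44 genes with an 8-base miR-451 site had a median of 0.21 (percentile 99.6). Genes with miR-92/25 sites had 0.05 (percentile 99.9, with 1 of 20 shuffled seeds as large, and inside the range with 8-base sites). The median of 5 reported messenger RNA targets of the Microprocessor, −0.77 (percentile 1.06), came from a list on which Auts2 (23 and 10 counts) and Myl9 (20 and 7) were called lower, while Dgcr8 and Kif1b (0.30) stood above 0. MicroRNA host transcripts had a median of −0.37 (9 measured, percentile 0.45), with Dleu2 (18 and 6 counts, −1.59) called lower and H19 at −0.37.

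Most red-cell genes differed little from the control. Embryonic globins (percentile 2.28, or 28.3 against length-matched lists) were led by Hbb-bh1 at −0.53, with Hbb-y at −0.25, and Hba-x at −0.09 by TMM but above 0 by total counts. Globin genes took 23.11% of the counts (23.08% to 23.14%). Among adult globins (median −0.19, percentile 3.2) Hbb-b1 stood at −0.71 and Hbb-b2 at 1.06, with the same doubt about near-identical copies. The values of Tfrc (−0.06), Slc4a1 (−0.09) and Klf1 (−0.06) stood below 0 by TMM and above 0 by total counts, as did Gata1 (−0.09). The membrane list had a median of 0.06 (percentile 98.9, or 96.3 against length-matched lists), with 1 of 25 genes called higher, Mpp1 (1.21). The heme list (−0.06, percentile 19.3), erythroid regulators (−0.08, percentile 6.45) and terminal maturation genes (−0.02, percentile 39.8) lay inside their random ranges and changed sign by total counts, although Trim58 was called lower (−1.11).

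All 82 cytosolic ribosomal protein genes were below 0 by TMM, 8 of them above 0 by total counts, and only Rpl30 (−2.53, uncertain as above) was called lower (percentile 0). Mitochondrial ribosomal proteins had 0 of 78 called (percentile 0). Of 28 histone genes 1 was called higher and 1 lower (percentile 0), with Hist1h4d at −0.30 and Hist1h2ae at −1.55. Ribosome biogenesis genes (−0.03, percentile 22.4, positive by total counts), snoRNA hosts (−0.10, percentile 19.4) and translation factors (−0.07, percentile 18.4, positive by total counts) lay inside their ranges. Glycolysis and hypoxia genes (0.14, percentile 99.7) and mitosis genes (0.09, percentile 99.6) lay above theirs, although 0 of 26 and 0 of 34 genes were called higher and 1 glycolysis and hypoxia gene lower. Here rho with gene length was 0.12, and the shortest length class had a median of −0.16.

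The remaining lists lay inside their random ranges except for the macrophage list, whose 4 measured genes had a median of −1.02 (percentile 2.29, or 5.11 against length-matched lists, and inside the range by total counts), with Cd68 at 17 and 5 counts. The others were apoptosis (0.05, percentile 72.9), interferon-stimulated genes (0.04, percentile 55), the integrated stress response (−0.08, percentile 11.5) and immediate early genes (−0.05, percentile 34), these last 2 positive by total counts, and S phase (0.00, percentile 61.5). Cell markers inside were endothelial (0.25, percentile 72.8), megakaryocyte (0.18, percentile 82.2), mesenchyme (0.01, percentile 45.7), neural (−0.21, percentile 19), cardiac (−1.12, percentile 3.30, but below the range at 1.64 when matched on length) and progenitor genes (−0.23, percentile 5.90). Myb, a transcription factor of definitive progenitors, had 11 counts in the control and 0 in the Ter119-low library, at least 3.89-fold lower, and Gata2 had 11 and 3 (ratio 3.46, interval 1.03 to 21.7). Of the other genes with the largest differences, Polr3g (76 and 198 counts, 1.29), a subunit gene of RNA polymerase III, and Slc25a20 (1.35) were higher, and Srgap3 (−1.71) and Igf2bp2 (−1.20) lower. Gate and genotype cannot be told apart in this comparison. Among genes at 10 or more CPM, only 17 were called higher and 14 lower.

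The third comparison, Drosha-null against Ter119-low, sets the 2 cKO populations side by side, which differ in gate and in Drosha abundance. Dgcr8 (1.56), Cdkn1a (1.89) and Ccng1 (1.52) were higher in the Drosha-null library, and progenitor genes were higher as a list, with a median of 1.51. Red-cell genes called lower included Slc25a37 (−1.79), Bpgm (−2.45) and, by TMM though not by total counts, Slc4a1 (−1.12). Of 10795 measured genes, 1170 were called higher and 636 lower.

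On the progenitor list 8 of 15 genes were called higher and 1, Kit (15 counts in the Ter119-low and 6 in the Drosha-null library), lower (percentile 100). Against the control, where 17 of its genes were measured, the list's median was 0.37 and lay inside the random range. Runx1 had 120 and 836 counts (2.47), Hhex, a homeobox gene of blood and endothelial precursors, 16 and 92 (2.17), and Csf2rb stood at 1.72 with fractional counts. Genes with miR-451 sites had a median of 0.53 (216 genes, percentile 100), with 61 (28.2%) called higher, and those with miR-92/25, miR-17/20/93 and miR-144-3p sites 0.26, 0.17 and 0.15, where for miR-92/25 and miR-144-3p 1 of 20 shuffled seeds each had an excess as large. The machinery list had a median of 0.53 (percentile 99.99), reported microRNA targets 0.42 (percentile 99.98) with Cdk6 at 1.96 and Ywhaz at 1.32, and 4 reported messenger RNA targets of the Microprocessor 1.34 (percentile 99.5, but inside the range when scaled without globin genes). For p53 targets 11 of 26 were called higher and 3 lower (0.65, percentile 100). The apoptosis list (0.30, percentile 95.5) stayed inside, with 7 of 23 genes called higher, among them Casp8 (2.64), and 0 lower.

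Lists below their random ranges were snoRNA hosts (−0.89), embryonic globins (−0.86, inside at percentile 3.93 when matched on length), cytosolic ribosomal proteins (−0.58, with 0 of 82 above 0 by TMM and 5 by total counts), heme and iron (−0.56), mitochondrial ribosomal proteins (−0.54), the red-cell membrane (−0.51), the integrated stress response (−0.45), erythroid regulators (−0.42) and ribosome biogenesis (−0.40). In them Hbb-bh1 stood at −1.18, Hemgn at −1.26, Tmem14c, a heme precursor transporter gene, at −1.32, Mrpl42 at −1.81, Snhg3 at −2.21 and Trib3 at −2.0. Lists above were glycolysis (0.37), mitosis (0.09), interferon-stimulated genes (0.72) and mesenchyme (0.95), the last 2 inside when matched on length and mesenchyme also by total counts or without globin genes, and cardiac genes (3.15, or 2.63 with genes at 0 counts at their bound). Fn1 had 621 and 2683 counts (1.79), Ttn 42 and 181 (1.77), and Mpo 0 and 23, at least 6.13-fold higher. Itga4 (4.74), Tspan8 (4.17), Rcan3 (3.32), Stk39 (2.97) and Ndrg2 (2.83) were among the highest genes, and Tinagl1 (−3.99), Mt2 (−3.61), Pklr (−2.57), Mt1 (−2.49) and Lmx1a (−2.30) among the lowest.

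Lists inside were histones (−0.24, percentile 5.86, positive by total counts), adult globins (−0.11, percentile 64.9, positive by total counts, and above the range at percentile 98.4 when matched on length), endothelial (0.64, percentile 77.1), macrophage (0.47, percentile 56.6), megakaryocyte (0.45, percentile 79.3), neural (−0.15, percentile 17.6, positive by total counts), S phase (−0.18, percentile 21.4, positive by total counts), terminal maturation (−0.26, percentile 6.56, positive by total counts), translation factors (−0.35, percentile 9.95), microRNA hosts (0.10, percentile 71.4) and immediate early genes (−0.15, percentile 31.6, positive by total counts). The log2 ratio again rose with gene length (rho 0.28), from a median of −0.40 in the shortest to 0.29 in the longest class. Total-count scaling raised log2 ratios by 0.34, less for genes at few counts, and the higher share of called genes went from 64.8% to 87.0%, or to 81.4% without globin, 75.5% without globin and ribosomal RNA and 82.9% from the authors' FPKM values.

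The cKO libraries shared genes that differed from the control. Of 10374 genes measured in both comparisons, 163 were called higher in both, where independent lists of 1080 and 236 would share 24.6, and 119 lower in both, where lists of 832 and 290 would share 23.3. A gene under 1 CPM in the control was measured in both only if both cKO libraries reached 1 CPM. This cut the higher lists from 1340 to 1080 and from 307 to 236 but left the lower lists whole. Part of the excess of genes higher in both may come from this filter. By total counts 56 were lower in both, against 6.33 for independent lists. In 100 simulations the cKO libraries differed from the control by counting noise alone, with the control counts held fixed. At most 0 higher and 1 lower genes were shared. These simulations leave out the counting noise of the control itself, so they give no baseline for the overlap. Both comparisons use the same single control library, so part of the excess may come from it. Another 9 genes were called in opposite directions, all higher in the Drosha-null and lower in the Ter119-low library.

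The authors' deposited table for the Drosha-null library lists 2964 genes at an FDR of 0.05 and an absolute log2 ratio of 1, of which 2633 were higher and 331 lower, and the authors' deposited table for the Ter119-low library lists 425, of which 269 were higher and 156 lower. Of these, 1628 and 371 were also called by size here. The authors' FDR compares the reads of 2 libraries, not the conditions, and the median log2 ratio over all genes in the authors' deposited table was 0.45 for the Drosha-null and 0.09 for the Ter119-low library.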

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

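Dleu2, the host transcript of miR-15a and miR-16-1, was singled out because its log2 ratio to the control had opposite signs in the 2 cKO libraries, both past the size rule. It was 1.59 in the Drosha-null library (18 counts in the control and 73 there, interval 0.85 to 2.44) and −1.59 in the Ter119-low library (6 counts, −3.29 to −0.27). With 1 library per group the difference was not tested.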

How the results depend on the processing

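Scaling without globin genes and ribosomal RNA, and matching on gene length, were chosen only after the results were seen. For the Drosha-null library against the control, the 1340 higher and 832 lower genes became 2501 and 294 by total counts, 2107 and 431 by total counts without globin genes, 2169 and 366 with the authors' deposited log2 ratio, 512 and 395 at 10 CPM, 2109 and 1890 at a fold of 1.5 and 450 and 149 at a fold of 4. The median of interferon-stimulated genes, 0.74, was 0.00508 at 10 CPM, where it lay at percentile 49.8. For the Ter119-low library against the control, the 307 higher and 290 lower genes became 17 and 14 at 10 CPM, 543 and 519 at a fold of 1.5 and 105 and 92 at a fold of 4, and the 7 lists below their random range became 3 at 10 CPM, where 24 of 31 lists had a percentile, and embryonic globins and microRNA hosts were lost. For the Drosha-null against the Ter119-low library, the 1170 higher and 636 lower genes became 2036 and 304 by total counts, 1798 and 411 without globin genes, 1786 and 369 from the authors' FPKM values, 1770 and 366 from the difference of the authors' log2 ratios, 406 and 255 at 10 CPM, 1963 and 1599 at a fold of 1.5 and 348 and 130 at a fold of 4, and the 10 lists above became 6 at 10 CPM, again with 24 lists left. Genes higher in both cKO libraries, 163, became 294 at a fold of 1.5, and genes lower in both, 119, became 229 at that fold and 56 by total counts. The 425 genes of the authors' deposited table for the Ter119-low library became 88 at an FDR of 0.001. With 8-base sites the medians of let-7 (0.23) and miR-15/16 (0.22) in the Drosha-null library against the control, and of miR-15/16 (0.17) against the Ter119-low library, lay above their random ranges, and that of miR-92/25 in the Ter119-low library against the control (0.0518) lay inside. Another scaling changed the sign of 19 of 154 named genes for the Drosha-null library against the control. It did so for 16 of 147 for the Ter119-low library against the control and 16 of 152 between the cKO libraries. None of these genes was past the size rule. That was fixed in advance, since the rule requires an absolute log2 ratio of 1 and the largest shift by a scaling was 0.43. Of 89 named genes past the rule for the Drosha-null library against the control, 74 stayed past it by total counts. Without globin genes 79 did, and with the authors' deposited log2 ratio 75. Of 79 against the Ter119-low library, 66, 71 and, from the authors' FPKM values, 67 stayed past it. The 18 lists outside their random range for the Drosha-null library against the control stayed outside under the other planned scalings. These were total counts, the median of ratios and total counts without globin genes. A scaling shifts a list and its random lists nearly alike, so these percentiles could hardly change and do not test the scaling. The medians themselves changed sign under another scaling for 6 of 31 lists. At 10 CPM adult globins were lost and microRNA hosts gained. Of the 10 lists outside for the Ter119-low library against the control, macrophage was lost by total counts, without globin genes and with 5 counts added. Of the 19 for the Drosha-null against the Ter119-low library, mesenchyme was lost by total counts and without globin genes, reported Microprocessor targets without globin genes and interferon-stimulated genes at 10 CPM, where microRNA hosts were gained below their range. For lists and sites the cause of these differences was not tested. The alternatives planned for files without counts were not run, because counts were present.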

Other observations

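The tests of gene length for ribosomal protein genes and for miR-451 sites, and that of other arrangements of the bases of the miR-451 site, were chosen only after the results were seen, as were the simulated mixtures under each scaling and the sex-linked genes named next. Y-linked transcripts and Xist, the RNA of the inactive X chromosome, were present in all 3 libraries. Xist had 1818 counts in the control, 2993 in the Drosha-null and 3958 in the Ter119-low library, and Tsix, transcribed from the opposite strand, had 96, 170 and 204, which may include Xist reads if counting ignored the strand. The Y-linked translation factor gene Eif2s3y had 236, 195 and 147 counts, and Kdm5d had 87, 61 and 88, whereas Ddx3y had 125, 283 and 148 and Uty had 41, 102 and 55. The Y-linked genes thus did not differ together in 1 direction. The sex of the pooled embryos is not in the labels.

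Ribosomal protein genes were lower in the Drosha-null library, and the log2 ratios of short genes were lower than those of long genes in general. Against other genes of matched length and expression (296 genes, median length 679 bp against 702 bp) the list's median of −0.82 lay at percentile 0, with a random median of −0.52 (−0.61 to −0.40), which argues against the length trend as the whole cause while it could account for part. The matched genes were less abundant, at a median of 244 CPM against 458. The 65 members with whole counts in every library had a median of −0.80 (−0.83 to −0.76), beside −0.98 for the other 17. This argues against reads split among counted genes as the whole cause. Whole counts cannot reveal shared reads that were given undivided to a single gene, and the counting program and annotation are not known. Reads shared with pseudogenes or paralogs in that way therefore stay open. Differences in RNA quality, library preparation or stage between single pools stay open, as does an effect of Drosha loss on these genes.

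Genes with miR-451 sites were higher in the Drosha-null library. Matching on gene length, 3' UTR length and expression left their median of 0.59 at percentile 100 (random median 0.13, 0.02 to 0.23). Of 179 other arrangements of the site's bases, 0 had an excess as large as 0.47. The highest, 0.355, was that of ACGGTTA, which is itself part of the 8-base miR-451 site AACGGTTA, and the next was 0.257. These values argue against gene length and base composition. RNA of other cells carrying such genes is argued against as the whole cause by the 73 site genes at 20 or more CPM in the control, whose median of 0.0991 lay at percentile 99.4 of matched sets (random median −0.09, −0.21 to 0.07). That median was smaller than over all site genes, but so was its random median, because the cut is on the control, the denominator of the ratio. The drop therefore cannot tell such RNA from other causes. Cardiac muscle genes (median 3.37, or 1.94 with genes at 0 counts at their bound) were also higher in the Drosha-null library. So was Pecam1 (3 and 55 counts), though the endothelial list lay inside its random range (percentile 89.9). The mesenchyme, megakaryocyte, macrophage and neural lists also lay inside theirs. Such RNA could account for part of the pattern and stays open for it. What remains is consistent with the hypothesis that targets of miR-451 accumulate where microRNA processing is lost, a hypothesis found and weighed in the same libraries, in which the microRNA itself was not analysed here.

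The Ter119-low library lay between the control and the Drosha-null library for many genes. With the control counts divided at random into parts of equal size, genes higher in the Drosha-null library stood 9.12% of the way to it by TMM (7.40 to 11.3, 525 genes), which argues against counting noise of the shared control. Genes lower there stood 19.9% of the way (16.2 to 23.2, 412 genes), and the intervals were also apart by the median of ratios (7.21 to 10.9 and 16.4 to 23.6), without globin genes (7.51 to 10.4 and 11.4 to 20.1) and without globin and ribosomal RNA (7.28 to 10.48 and 14.1 to 22.1), but they overlapped by total counts (8.89%, 7.65 to 10.2, and 12.9%, 7.35 to 17.8). For a share of Drosha-null-like RNA as the only difference, the scalings disagree. A simulated mixture of 10% gave 12.04% and 13.7% by TMM and 10.48% and 10.7% without globin genes, closer together than the values here. But a simulated mixture of 20% gave intervals that were apart by the median of ratios (23.2 to 25.1 and 25.4 to 28.6), though less far apart than here. Total counts returned 9.58% and 9.84% for the 10% mixture. That was fixed in advance, because the mixture was built from shares of total counts. Total counts left the intervals here overlapping. The test cannot decide this, and such a share, alone or beside other differences, stays open. Noise of the single control library beyond counting, the sex mix of the pools, and the gate, which differs together with genotype, also stay open. Drosha itself stood 40.5% of the way by TMM, with a simulated counting interval of 23.2 to 54.9.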
